A study of Mus musculus with 84 samples.

How the data were processed

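RNA was measured by sequencing in the central nucleus of the amygdala (CeA), a brain nucleus of mostly inhibitory neurons that takes part in stress and ethanol drinking. The 84 animals, 43 females and 41 males, were heterogeneous stock Collaborative Cross (HS-CC) mice, an outbred population bred from the Collaborative Cross founder strains. Per the labels' protocols, the mice chose between water and 10% ethanol for 13 weeks, were euthanized in 4 passes, and gave 1 library each. The nucleus was laser-dissected from thionin-stained frozen sections, libraries were stranded and selected for poly(A), only RNA with a quality score above 7 was used, and up to 6 libraries shared a lane, per the labels' protocols. Per the same protocols, up to 3 animals came from 1 family. Family and lane are not given for each animal in the sources used here, so neither could enter a fit, and the animals were not fully independent.

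The deposited values were counts of reads per gene without normalization, per the labels. FastQC, STAR, Subread featureCounts 1.6.0 and DESeq2 were the tools named for making them, on mouse genome build GRCm38 (mm10), per the submitters' processing notes. The strand setting of the counting, the annotation release and any filter are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene could not be told apart, and genes with near-identical copies, such as Hba-a1, Hbb-bs and Vcp-rs, carry uncertain values. The table listed 43629 genes by Ensembl identifier with a symbol and exon positions, and all gene positions given are those of the table. All 84 sample columns held whole numbers. A further 3 columns of undetermined reads and 5 empty columns were not used. In the table, 27 symbols had been turned into dates, and all 27 were recovered through their identifiers. A reference table of gene names matched 42462 of the identifiers. No count was recorded for 12800 genes, and all 37 mitochondrial genes were listed at 0.

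Total counts per library ran from 24118965 to 42036566 with a median of 31573088.5. The range was 24118965 to 36924667 in females and 24829435 to 42036566 in males, and each library had counts for 20332 to 21785 genes. Precision is given as the median SE of a log2 change per 0.5 rise in mean preference, which was 0.11 over all animals, 0.14 in females and 0.17 in males. For week 13 preference in females it was 0.11. These SE cover the spread between animals.

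Each animal's sex and its weekly preference ratio and ethanol intake came from the labels. Preference is the volume drunk from the ethanol tube over the volume drunk from both tubes, and intake is given in g of ethanol per kg of body weight. Mean preference was the mean of the 13 weekly ratios. Replicate numbers follow the order in which the samples are listed and pair nothing. Sample titles carry sample-sheet numbers that form 4 ascending runs, with 9, 9, 10 and 15 females and 9, 9, 7 and 16 males. These runs were taken as possible batches, since no library date is given in the sources used here. The sex labels were checked: the lowest Xist count in a female was 4114 and the highest in a male 126, while the highest Ddx3y count in a female was 11 and the lowest in a male 400.

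Genes were kept by edgeR's filterByExpr with the sexes as groups, a minimum count of 10 and a minimum total of 15, which left 16320 genes. Counts were scaled by TMM factors and fitted with edgeR's robust quasi-likelihood model. Coefficients were tested with its F-test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Slopes are log2 changes per 0.5 rise in preference ± SE, where SE is the size of the change over the square root of F, and per 10 g/kg where intake took its place. Mean, week 1 and week 13 preference were each fitted in all 84 animals with sex as a term, in females alone and in males alone. A sex by mean preference term and the sex difference itself were fitted in all 84 animals. CPM values used TMM-scaled totals, with a prior count of 2 on the log2 scale. The mean log2 CPM of a gene is edgeR's average log2 CPM over the animals of the fit, which 1 library with many counts can raise, as for Slc6a3 (1.86).

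In all, 35 gene lists were written with the design, of cell types, neighbouring regions, signalling and RNA quality. The list of mitochondrially encoded genes had 0 measured members and was not tested, so 34 lists were. They were tested with limma's camera at a preset inter-gene correlation of 0.01 on voom values, again with an estimated correlation, and with fry, adjusted over the lists. Medians given for lists are of voom slopes unless edgeR is named. Counts of list members past the threshold are given over all genes and adjusted over the list alone. The score of a list in a library was the mean z-score of its members' log2 CPM. Of the 14 choroid plexus members, 11 had a median CPM of at least 1 in these libraries, as had 32 of the 38 measured ependymal members.

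Genes were named by a rule. For mean preference the rule took up to 15 higher and 15 lower genes past the threshold with a mean log2 CPM of at least 1, or, where fewer than 10 passed, the 10 with the smallest p. For week 1, week 13 and the sex by preference term it took the 10 with the smallest p, and for sex the 10 on each side outside the X and Y lists. From each list it took up to 5 members past the threshold over all genes or over the list alone, and 4 of a list past the list test. Crh, Crhr1, Sst, Prkcd, Nts, Tac2, Pdyn, Penk, Npy, Oprk1, Gabra2, Grin2b and Fkbp5 were named whatever their values. Called genes with a lower mean, and genes named for 1 library, were chosen after their values were seen, and of the lists past the list test only those central to the results had their 4 members named, a choice also made after the list results were seen.

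Drinking was compared with 2-sided permutation tests of 100000 resamples, by permuting sex labels or flipping signs within animals, and the smallest p they can give is 1e-05. Correlations are given as Pearson's r and Spearman's rho with permutation p, again without the 2 animals farthest from the median of the x axis, and within each run of sample-sheet numbers. The slopes of mean preference in females and males were correlated across 16320 genes and set against shuffles of preference among the males. Gene and list counts were set against 99 shuffles of the animals plus the real order, 100 in all.

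The fits of mean preference in all animals, females and males, of week 13 preference in females and of sex were tested on simulated counts with known changes. The other fits were not. At a log2 change of 1 over the tested step, edgeR recovered 92.5% of changed genes for mean preference in all animals, 71.6% in females and 73.1% in males, and 98.5% for sex. At 0.5 the shares were 61.2%, 43.3%, 28.4% and 80.6%. For week 13 preference in females the shares were 83.6% at 1 and 62.7% at 0.5. These counts held 200 changed genes and were drawn for each gene independently, without variation shared between genes. In the real data, where few or no genes passed, the shares could therefore be lower. The list test recovered the 1 shifted list and called 0 of the others, in counts simulated without correlation between genes. That simulation therefore could not show how often the preset correlation calls lists by chance in these data.

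The design, the lists, the naming rule and most alternatives were fixed before the data were examined. Those alternatives were DESeq2's Wald test, limma-voom, DESeq2 size factors in edgeR, no low-count filter, a filter at 1 CPM, run as a covariate, surrogate variables from sva (at most 10), scores of the 2 main neighbouring regions as covariates, rank of preference, ethanol intake in place of preference, and leaving out the 2 animals with the most extreme preference. Added after seeing the data were the choroid plexus score as a covariate, leaving out the 5 libraries with the highest score, leaving out single libraries, and a test of whether week 13 slopes differ by sex. In all, 114 fits were run. Genes of the choroid plexus list have no value under the choroid covariate, which is made from them. Co-expression networks and single-variant effects were not analysed here. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Single-gene results of 2 genes are not reported here.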

Results

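Gene expression in the CeA was measured in 84 HS-CC mice, 43 females and 41 males, after a 13-week choice between water and 10% ethanol. Each mouse gave 1 library, with 24118965 to 42036566 counts and a median of 31573088.5, and 16320 genes had enough counts to be tested. The design asked how expression relates to preference for ethanol in week 1, in week 13 and on average over all weeks, in all animals and in each sex. Mean preference was 0.272 ± 0.17 (SD, n = 43) in females and 0.21 ± 0.152 (SD, n = 41) in males. The study counted 12 females and 8 males with a preference of at least 0.5, while 5 females and 1 male reached 0.5 in the mean over all weeks and 10 females and 4 males in week 13. In week 1 they were 5 and 3, and in the week of each animal's highest ratio 18 and 8, so none of these measures gave the study's counts.

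The sexes were first compared in drinking, because the labels name a sex difference in preference. Mean preference was 0.0622 higher in females than in males, a difference that did not pass (2-sided permutation p = 0.0816). Mean ethanol intake was 6.07 ± 3.65 g/kg in females and 3.66 ± 2.76 g/kg in males (SD), a difference of 2.41 g/kg (p = 0.00114). Preference in females rose from 0.205 in week 1 to 0.326 in week 13, by 0.12 on average and in 32 of 43 animals (2-sided sign-flip permutation p = 0.00011). In males it was 0.201 in week 1 and 0.219 in week 13, a mean change of 0.0177 with 22 of 41 higher (p = 0.566). The change in females exceeded that in males by 0.103 (permutation of sex, p = 0.0189). Between the means of weeks 1 to 2 and of weeks 12 to 13, the change was 0.0743 in females (p = 0.0114) and 0.0215 in males (p = 0.378), and their difference of 0.0529 no longer passed (p = 0.161).

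Animals kept part of their rank from week 1 to week 13, one of 6 relations computed between drinking measures. In females Pearson's r was 0.468 (permutation p = 0.00145, adjusted 0.00217) and Spearman's rho 0.474 (p = 0.00121, adjusted 0.00145). Without the 2 animals farthest from the median, r was 0.404, and within the 4 runs of sample-sheet numbers it was 0.69, 0.717, 0.66 and 0.276. In males r was 0.465 (p = 0.00232, adjusted 0.00278) and rho 0.592 (p = 8e-05, adjusted 0.00012). Their r was 0.508 without the 2 extreme animals and 0.536, 0.597, 0.665 and 0.315 within the runs.

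**Figure D1:**
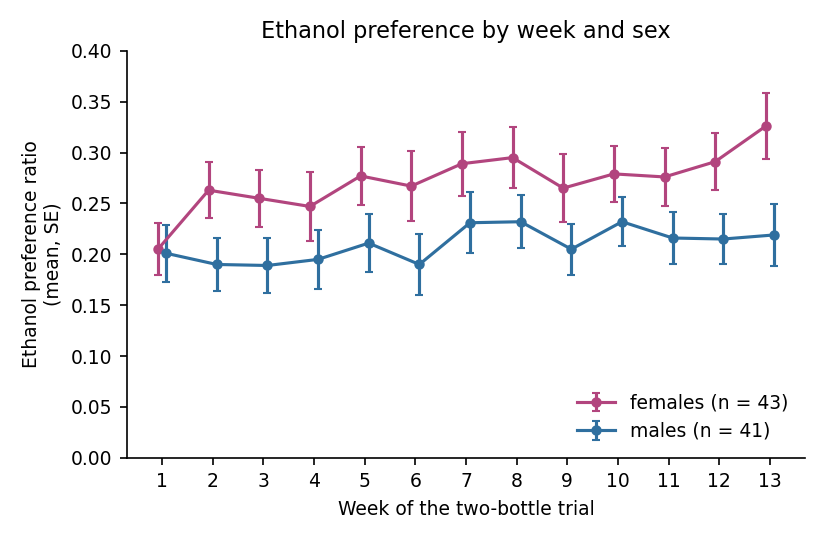
Ethanol preference ratio (y axis) by week of the trial (x axis) in 43 females and 41 males, as points at the mean with bars of 1 SE. The female mean went from 0.205 in week 1 to 0.326 in week 13 and the male mean from 0.201 to 0.219.

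Mean preference over all weeks was set against expression in all 84 animals to ask which CeA genes go with chronic drinking. The genes with the smallest p included Dsg2, which encodes the desmosome protein desmoglein 2, with a log2 slope of 1.17 ± 0.31 per 0.5 rise in preference, and Hdc, which encodes the enzyme that makes histamine, with 1.26 ± 0.35. Gon7 (-0.67), Ebna1bp2 (-0.20) and Slc6a3 (-2.68) sloped down, and Syce2 (0.84), Srl (0.86), Tuba8 (0.63), Ccdc30 (0.26) and Tm4sf1 (0.55) sloped up. Adjusted p-values of these genes in edgeR were 0.789 or higher. The smallest over all genes was 0.192, of Sebox (1.69 ± 0.36), which lay below a mean log2 CPM of 1 and was named after its values were seen. Among peptides of CeA neurons, Crh, which encodes corticotropin-releasing hormone, had a slope of -0.47 ± 0.23 (edgeR unadjusted p = 0.0464, adjusted 1). Slopes of the dynorphin gene Pdyn (-0.70), the enkephalin gene Penk (-0.56), Prkcd (-0.51), Tac2 (-0.35), Nts (-0.31) and Sst (-0.06) also lay below 0, and that of Npy (0.23) above. Oprk1 (-0.22), Fkbp5 (-0.19), Crhr1 (-0.03), Gabra2 (0.14) and Grin2b (0.03) did not pass either. Over all 16320 genes, edgeR called 0 at an adjusted p under 0.05 and 643 at an unadjusted p under 0.05, DESeq2 0 and 669, and limma-voom 0 and 544.

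Of the 11 gene lists that camera called for mean preference in all animals with its preset correlation, those of cells that line the ventricles had the largest median slopes. Choroid plexus genes, which belong to the epithelium that secretes cerebrospinal fluid, had a median slope of 1.79 (camera adjusted p = 1.59e-12, adjusted p = 0.354 with an estimated correlation), and ependymal motile cilium genes one of 0.70 (4.52e-20, and 0.354). Dnah2 (0.88), Dnah10 (1.25), Enkur (0.78) and Hydin (1.03) led the ependymal list. Microglia genes sloped down with a median of -0.16 (1.46e-08, and 0.354), with Laptm5 (-0.24), C1qa (-0.28) and Cd68 (-0.17) among the first. Median slopes of GABA signalling genes (-0.071; 0.0072, and 0.519), which include Gad1 (-0.28) and Slc32a1 (-0.35), and of CeA neuropeptides and receptors (-0.075; 0.0374, and 0.639) were small. Striatal medium spiny neuron genes sloped down (-0.32; 0.00012, and 0.859) and cortical and basolateral excitatory neuron genes up (0.27, or 0.081 in edgeR; 0.0017, and 0.791). The remaining calls were primary cilium (0.045; 0.00137, and 0.519), oligodendrocyte precursor (-0.11; 0.00137, and 0.519), astrocyte (-0.057; 0.0208, and 0.869) and cytosolic ribosomal protein genes (-0.059; 0.000488, and 0.882). All 11 calls rested on the preset correlation, since 0 lists passed with an estimated one or with fry, and 0 members passed adjusted over the list alone or over all genes.

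The other lists did not pass in all animals. Median slopes were -0.044 for glutamate receptors, 0.0044 for voltage-gated and leak ion channels, -0.030 for monoamine, acetylcholine and cannabinoid signalling, -0.0056 for the presynaptic release machinery and 0.0040 for the postsynaptic scaffold. They were 0.043 for immediate early genes, -0.039 for glucocorticoid-responsive genes, -0.044 for the circadian clock, 0.031 for alcohol and aldehyde metabolism, -0.024 for antioxidant and glutathione genes and -0.027 for heat shock and the unfolded protein response. Cell type lists gave 0.030 for endothelial and mural, -0.13 for leptomeningeal and fibroblast, 0.11 for erythrocyte and -0.19 for thalamic, hypothalamic and medial amygdala neuron genes. Innate immune genes had a median of 0.0026, nuclear-encoded oxidative phosphorylation -0.024, nuclear-retained long RNAs 0.15, chromatin modifiers 0.015 and the extracellular matrix of the perineuronal net -0.0022. Y-linked and X escape genes gave 0.075 and 0.029. The sign of the median differed from that of the list test for the ion channels and the postsynaptic scaffold, and from that of the mean for heat shock genes (mean 0.0033) and the perineuronal net (mean 0.013). For myelinating oligodendrocyte genes the voom median was 0.028, while 22 of 25 members had negative slopes in edgeR.

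**Figure D2:**
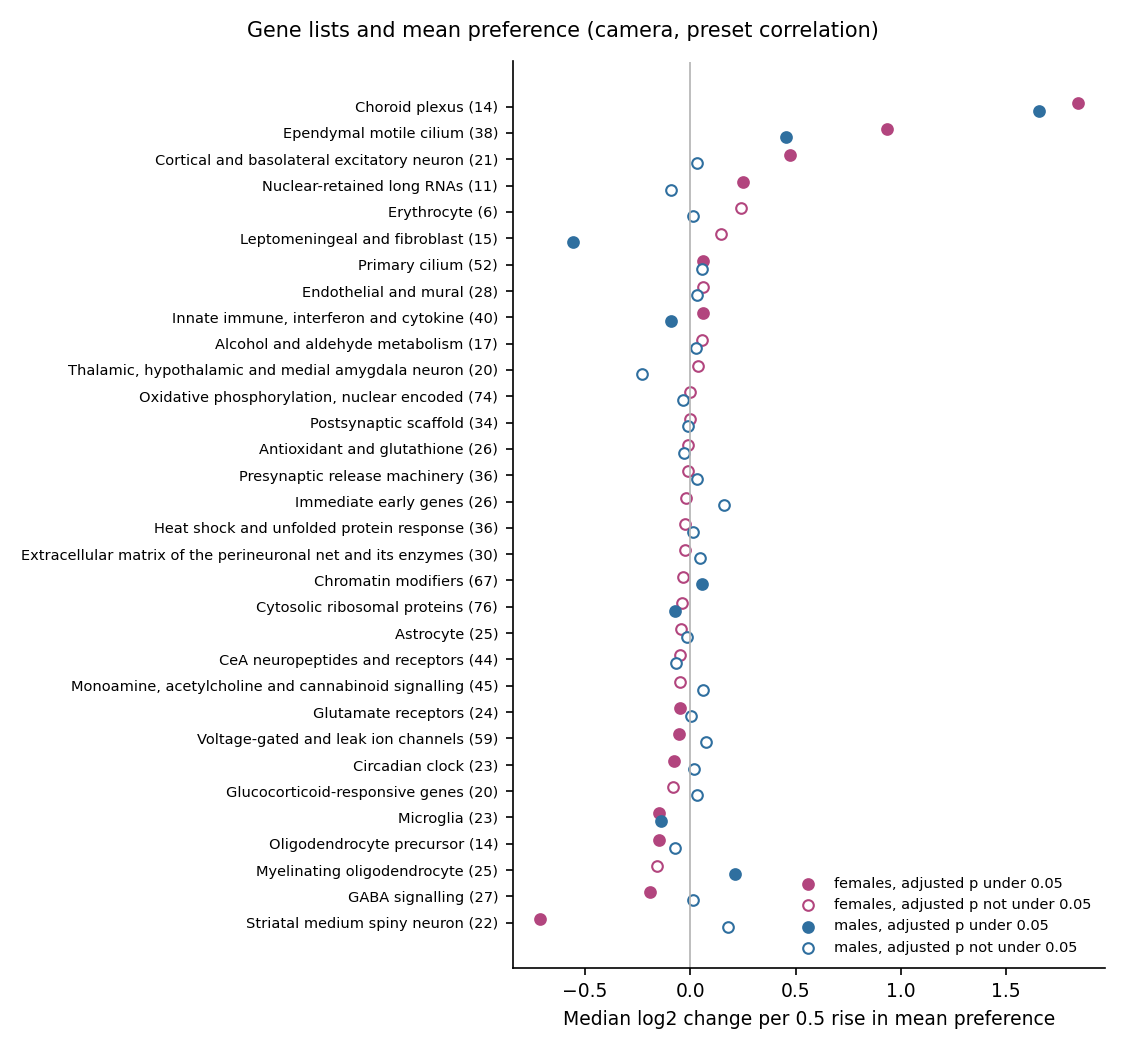
Median log2 change per 0.5 rise in mean preference (x axis) of the gene lists (y axis) in females and males. Choroid plexus genes had the highest medians, 1.84 in females and 1.66 in males, and no list passed with an estimated inter-gene correlation. Medians are of voom slopes, and in edgeR the male median of the choroid plexus list was far smaller.

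In females alone, mean preference was set against expression in 43 animals. Pqlc3, which encodes a membrane transporter-like protein, had a slope of 1.41, Sema3b 1.41, Dsg2 1.52, Hdc 1.69, Ggt5 0.93, Llgl2 1.29, Tm4sf1 0.73 and Camk1g -0.51, all with an edgeR adjusted p of 0.477. Choroid plexus genes Kl (2.62), F5 (2.49), Kcnj13 (2.23), Cldn2 (2.75) and Clic6 (1.76) were among 13 of 14 past the threshold adjusted over the list alone, and 0 over all genes. With surrogate variables as covariates these 5 slopes changed sign (-0.11, -0.33, -0.53, -0.41 and -0.17), as did those of Adh1 (-0.0078), Cfap65 (-0.16), Adcy5 (0.012) and Pde1b (0.049), while Dnah11 turned to -0.074 and Adh1 to -0.11 without the 5 libraries with the highest choroid plexus score. Likewise 13 of 38 ependymal genes passed adjusted over the list alone, including Dnah2 (1.21), Cfap65 (1.57), Tekt1 (1.36), Cfap44 (1.36) and Dnah11 (1.70), again with 0 over all genes. Members of a list vary together, so these counts are not separate results. The choroid plexus score had r = 0.24 with mean preference in females (permutation p = 0.123), and 0.088 without the 2 animals farthest from the median. For the ependymal score r was 0.29 (permutation p = 0.0584) and 0.178. Adh1, an alcohol dehydrogenase gene, had a slope of 1.95 and Homer3, of the postsynaptic scaffold, 0.88, each the 1 member of its list past that adjustment. Over all genes edgeR called 0 (1135 at an unadjusted p under 0.05), DESeq2 0 (1185) and limma-voom 0 (847).

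Camera called 13 lists in females with the preset correlation. Choroid plexus (1.84; adjusted p = 1.55e-07, adjusted p = 0.546 with an estimated correlation) and ependymal genes (0.94; 1.39e-16, and 0.546) were higher, and striatal medium spiny neuron genes lower (-0.72; 4.54e-10, and 0.546), among them Penk (-0.93), Gnal (-0.55), Adcy5 (-0.58) and Pde1b (-0.57). GABA signalling (-0.19; 0.000133, and 0.50) and microglia genes (-0.15; 0.000112, and 0.546) sloped down, and cortical and basolateral genes up (0.48, or 0.22 in edgeR; 0.00412, and 0.626). The other calls were glutamate receptors (0.0359), ion channels (0.0278), circadian clock (0.0133) and oligodendrocyte precursor genes (0.0133) downwards, and primary cilium (0.0195), innate immune (0.036) and nuclear-retained genes (0.0168) upwards, with 0.546 to 0.742 under an estimated correlation. Fry called 0.

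In males, Tagap, which encodes a GTPase-activating protein of T cells, had a slope of -1.37 and Fcrls, a gene of microglia, one of -1.22. Tmem181a (0.55), Gsdmd (-0.55) and the MHC class II gene H2-Eb1 (-1.66) followed, all with an edgeR adjusted p of 1. Fcrls was the 1 microglia gene past the threshold adjusted over the list alone. Leptomeningeal and fibroblast genes had a median of -0.56 (camera adjusted p = 0.000292, adjusted p = 0.915 with an estimated correlation), with Slc22a6 (-1.94), Fmod (-1.50), Foxc2 (-1.78) and Slc13a3 (-0.95) first. Microglia genes such as Itgam (-0.35) sloped down (-0.14; 0.000292), innate immune genes down (-0.093; 0.0134) and ribosomal genes down (-0.071; 0.000527). Ependymal (0.46; 0.000292), myelinating oligodendrocyte (0.21; 0.0134), chromatin modifier (0.054; 0.0141) and choroid plexus genes (1.66; 0.000163) sloped up. All 8 calls had an adjusted p of 0.915 with an estimated correlation, and fry called 0. The edgeR median of the choroid list was 0.059 with 9 of 14 members positive, so its size in males depended on the tool. Over all genes edgeR called 0 (270 at an unadjusted p under 0.05) and limma-voom 0, while DESeq2 called 2, Tagap and Npw (315 unadjusted).

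Whether the relation to mean preference differed by sex was tested with its own term. Among the genes with the smallest p were Gatc, with a male minus female slope of 0.35, the melanocortin precursor gene Pomc (-2.45) and Sema3b (-2.13), all with an edgeR adjusted p of 0.999. Striatal medium spiny neuron genes had a median difference of 0.91 (camera adjusted p = 4.71e-08, adjusted p = 0.933 with an estimated correlation), and leptomeningeal genes one of -0.86 (0.00227, and 0.933). For genes, edgeR called 0 (529 at an unadjusted p under 0.05), limma-voom 0 (412) and DESeq2 1, Npw (550). Across 16320 genes, which are not independent replicates, slopes in females and males had r = 0.249, and 45 of 100 orders of the males, the real one included, gave an r as large in size. With run as a covariate r was 0.0785 (permutation p = 0.78), and over the 10653 genes with a mean log2 CPM of at least 3 it was -0.059 (p = 0.85).

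Week 1 preference asked which genes go with the first choice of ethanol. The 5 genes called in all animals were Npw, the gene of neuropeptide W (2.60 ± 0.37, edgeR adjusted p = 7.15e-06), Cd28, a co-stimulatory receptor of T cells (1.94 ± 0.32, 0.000241), Ppm1j (1.64 ± 0.28, 0.000416), S100a3 (1.44 ± 0.29, 0.0127) and Tdrd9 (1.11 ± 0.23, 0.0154). The same 5 and Epcam, an epithelial adhesion gene (2.07 ± 0.42, 0.0298), were called in males, where Npw had a slope of 3.46 ± 0.48 (9.73e-05). Npw (ENSMUSG00000071230) lies on chromosome 17 from 24657330 to 24658457 and Cd28 (ENSMUSG00000026012) on chromosome 1 from 60716800 to 60773359 of GRCm38. All 6 lay below a mean log2 CPM of 1 and were named after their values were seen. Every call rested on 1 library, male replicate 39, whose week 1 preference of 0.633 was the second highest. It held 1216 counts of Npw (39.9 CPM), against 66 counts (2.1 CPM) in the next library, female replicate 42. Without male replicate 39, Npw had a slope of -0.26 in all animals and -0.96 in males, and edgeR called 0 genes in all animals (282 at an unadjusted p under 0.05) and 0 in males (559). Limma-voom called 0 with it as well (438 and 705 unadjusted), and DESeq2 called 4 and 3.

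**Figure D3:**
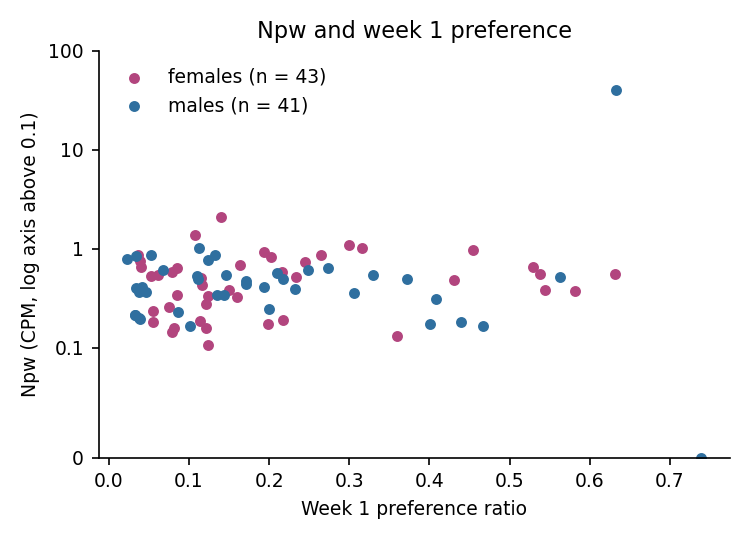
Npw expression in CPM (y axis, a log axis above 0.1) against week 1 preference ratio (x axis), with 1 point per library for 43 females and 41 males. Male replicate 39 stood at 39.9 CPM and the next library at 2.1 CPM.

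Some activity-regulated genes passed for week 1 preference over their list alone, but 0 of them without male replicate 39. Bdnf (0.81), Fosb (0.68), Nptx2 (0.83), Fos (0.69) and Gadd45b (0.43) were among 8 of 26 immediate early genes past the threshold adjusted over the list alone in all animals, and 6 in males, with 0 over all genes. Without male replicate 39 these counts were 0 in all animals (8 at an unadjusted p under 0.05) and 0 in males (4), with positive slopes in 25 and 24 of the 26. The median edgeR slope of the list went from 0.399 to 0.3 in all animals and from 0.457 to 0.353 in males, so most of its size stayed. The list was called upwards by camera in all animals (0.33; adjusted p = 7.06e-12, adjusted p = 0.576 with an estimated correlation), in females (0.30; 0.000122, and 0.893) and in males (0.36; 1.1e-06, and 0.854). Scores of this list were mostly positive in the first run of sample-sheet numbers and mostly negative in the fourth. For week 1 the list was not tested with run as a covariate or against shuffled orders, so run and chance stay open. Male replicate 39 also had the highest Bdnf (median 28.9 CPM), Nptx2 (479 CPM, median 57.4), Npy (395, median 64.6) and Fosb (61.3, median 18). Matn4 (-0.28) in all animals and Fcrls (-1.14) in males passed over their lists alone. In females edgeR called 0 genes (369 at an unadjusted p under 0.05), DESeq2 0 (411) and limma-voom 0 (360), with Ano10 (0.37), Slc2a6 (0.44) and Slc6a3 (-4.37) first. Slc6a3 was called with the rank of preference (-4.60, edgeR adjusted p = 0.00311), and 230 CPM of it lay in female replicate 15.

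Week 13 preference asked which genes go with drinking at the end of the trial, close to the time of dissection. In females 6 genes rose with it: Corin, a protease that activates natriuretic peptide (3.48 ± 0.62, edgeR adjusted p = 0.0131), Sema3b, a secreted semaphorin (1.48 ± 0.27, 0.0131), Pqlc3 (1.35 ± 0.26, 0.0175), Col8a1, a collagen chain (2.03 ± 0.39, 0.0175), Rrh, the opsin gene peropsin (2.94 ± 0.57, 0.0178), and Sptlc3, of sphingolipid synthesis (3.15 ± 0.64, 0.0333). On GRCm38, Corin (ENSMUSG00000005220) lies on chromosome 5 from 72300025 to 72504473, Sema3b (ENSMUSG00000057969) on chromosome 9 from 107597674 to 107609229, and Col8a1 (ENSMUSG00000068196) on chromosome 16 from 57624258 to 57754737. Pqlc3 (ENSMUSG00000045679) lies on chromosome 12 from 16988648 to 17000408, Rrh (ENSMUSG00000028012) on chromosome 3 from 129804408 to 129822505, and Sptlc3 (ENSMUSG00000039092) on chromosome 2 from 139493913 to 139637674. Corin, Rrh and Sptlc3 lay below a mean log2 CPM of 1 and were named after their values were seen. Slopes of Sema3b within the runs of sample-sheet numbers were 0.88, 1.58, 0.17 and 2.07, and those of Corin 1.73, 2.65, -0.36 and 1.71. DESeq2 called 2.1e2 genes (rounded), 15 of them lower and the others higher, and limma-voom 0 (1415 in edgeR and 1176 in limma-voom at an unadjusted p under 0.05). Leaving out female replicate 38 (Sema3b 1.17, Corin 2.87) or female replicate 17 (1.36 and 3.38) left edgeR with 0 calls (950 and 1223 unadjusted).

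Over their lists alone, more genes of the ventricle lining passed in females at week 13. Choroid plexus genes F5 (3.07), Kl (2.84), Cldn2 (3.16), Kcnj13 (2.51) and Clic6 (1.88) were among 13 of 14 higher adjusted over the list alone, and Tekt1 (1.41), Cfap65 (1.54), Dnah2 (1.10), Cfap44 (1.35) and Dnah10 (1.82) among 29 of 38 ependymal genes, with 0 over all genes in both. Of the 22 striatal medium spiny neuron genes, 18 were lower, led by Gpr6 (-1.55), Pde1b (-0.67), Rarb (-0.93), Rasgrp2 (-0.88) and Pde10a (-1.06), with 0 over all genes. Crh was lower (-0.79) and its receptor gene Crhr2 higher (0.77), the 2 neuropeptide list members past that adjustment. Crhr2 was highest in female replicate 38 and male replicate 33, the 2 libraries with the highest choroid plexus score, and its slope was 0.24 with that score as a covariate. Adh1 (1.72) and Acss3 (1.12) of alcohol metabolism, Enpp2 (2.26), Mmp2 (1.16), Igf2 (1.34) and Pltp (0.62) passed over their lists alone as well. Each of them, too, was highest in 1 of the 5 libraries with the highest choroid plexus score. Enpp2 had 5672 CPM in male replicate 33 and 5454 in female replicate 38, against a median of 234.6. Camera called 11 lists, among them choroid plexus (2.23; adjusted p = 1.02e-14, adjusted p = 0.352 with an estimated correlation), ependymal (0.94; 9.39e-23, and 0.352) and striatal genes (-0.72; 2.38e-13, and 0.59).

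The choroid plexus score of a library, one of 256 relations of list scores to drinking, had r = 0.403 with week 13 preference in females (permutation p = 0.00787, adjusted 0.973; rho 0.376, p = 0.013, adjusted 0.925), and none of the 256 passed. Without the 2 animals farthest from the median r was 0.336, and within the runs it was 0.508, 0.752, -0.186 and 0.325, so it did not hold in the third run. In males r was 0.00264 (p = 0.987) and rho -0.0817 (p = 0.609), both adjusted to 0.963 or higher, r was -0.167 without the 2 extreme animals, and the runs gave -0.264, 0.388, -0.231 and -0.112. Male slopes of the 6 genes lay between -0.57 for Corin and 0.32 for Sptlc3. Tests of the sex difference gave edgeR adjusted p-values of 0.458 for Corin (difference -4.05, unadjusted p = 0.000225) to 0.639 for Sptlc3, so the slopes were not shown to differ by sex.

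**Figure D4:**
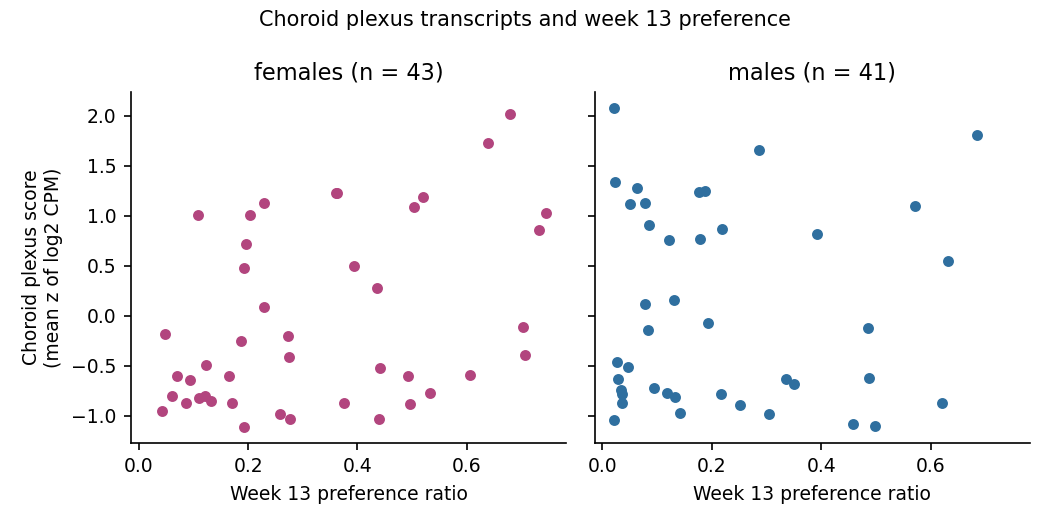
Choroid plexus score, the mean z-score of 14 genes (y axis), against week 13 preference ratio (x axis) with 1 point per library for 43 females and 41 males. The correlation was 0.403 in females and 0.00264 in males.

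In all animals Dsg2 (0.96), Hdc (1.06) and Srl (0.73) were among the genes with the smallest p for week 13 preference (smallest edgeR adjusted p 0.515), and edgeR called 0 genes (979 at an unadjusted p under 0.05), DESeq2 0 (998) and limma-voom 0 (676). In these fits Kl (1.64), F5 (1.58), Sostdc1 (1.22), Cldn2 (1.70) and Kcnj13 (1.43) were among 12 of 14 choroid genes, and Dnah2 (0.74) and Cfap44 (0.88) among 17 of 38 ependymal genes, past the threshold adjusted over the list alone, with 0 over all genes. In males the smallest p was that of Npw (edgeR adjusted p = 0.467), highest in male replicate 39. The aldehyde dehydrogenase gene Aldh3a1 (-3.09), the oxytocin gene Oxt (-4.29) and Vcp-rs (-3.65) had larger ones, each with an edgeR adjusted p of 0.779. Oxt passed adjusted over its list alone. Among males, Aldh3a1 was highest in male replicate 33 (56.5 CPM, median of all libraries 0.586), whose week 13 preference was 0.022. Oxt was highest among them in male replicate 22 (220 CPM, median of all libraries 1.26), whose week 13 preference was 0.023. Striatal medium spiny neuron genes had positive slopes in 22 of 22 members in males (0.39, or 0.96 in edgeR; camera adjusted p = 1.56e-05, adjusted p = 0.731 with an estimated correlation), against -0.72 in females. These genes mark a neighbouring region and vary together, so the 22 slopes are not separate results. The score of this list was highest in male replicate 28 (2.33, week 13 preference 0.498) and female replicate 10 (2.11, week 13 preference 0.11). Whether week 13 slopes of lists differ by sex was not tested. For males edgeR called 0 (610 at an unadjusted p under 0.05), limma-voom 0 (500) and DESeq2 2, Npw and Vcp-rs (678).

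Ethanol intake in place of mean preference gave more calls in females. Pqlc3 (1.46 ± 0.26 per 10 g/kg, edgeR adjusted p = 0.0174), Llgl2 (1.40), Eps8l2 (1.29), Col8a1 (1.98), Dsg2 (1.57), Adh1 (1.98) and the olfactory marker gene Omp (3.41) were among 2.1e2 genes (rounded), 3 of them lower and the others higher. Of these, 132 were also among the DESeq2 calls for week 13 preference, which used the same females. Only 2 choroid plexus list members and 7 ependymal members were among them, while 95.1% of the higher genes had an r of at least 0.5 with the choroid plexus score in males, against 7.35% of all tested genes. In all animals 8 genes were called, including Sebox (1.72), Dsg2 (1.33), Hdc (1.41) and Omp (2.32), and in males 0 (240 at an unadjusted p under 0.05). With the choroid plexus score as a covariate edgeR called 0 in females and 0 in all animals (832 and 479 unadjusted), and without the 5 libraries with the highest score 1 in each. Omp had 24.5 CPM in female replicate 7 against 2.39 in the next library.

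Sex itself was compared to check the labels and to show what separate fits rest on. The Y-linked genes Ddx3y (9.91), Kdm5d (9.78), Eif2s3y (9.71) and Uty (9.67) were higher in males, and Xist, the RNA that silences 1 X chromosome, was lower (-10.11). The X escape genes Eif2s3x (-0.56), Kdm6a (-0.40), Kdm5c (-0.35), Ddx3x (-0.30) and Pbdc1 (-0.26) were also lower in males, each with an edgeR adjusted p of 0.000301 or less. Ddx3x differed by -0.31, -0.22, -0.32 and -0.33 within the runs. Of the 15 genes called by edgeR, 6 were higher and 9 lower in males (622 at an unadjusted p under 0.05), while DESeq2 called 19 and limma-voom 12. Outside the X and Y lists only 4 passed, a gene model, Slc6a3, Omp and Ddx4. The dopamine transporter gene Slc6a3 (-3.03 ± 0.53, edgeR adjusted p = 0.000183) rested on female replicate 15, and was -0.18 without that library. Omp (-1.90) was -0.86 without female replicate 7 and no longer passed (adjusted p = 0.425), while Ddx4 (0.68) was 0.60 without male replicate 36. Greb1 (0.91) and Pmch (2.20) passed adjusted over their list alone, but Pmch had 1040 CPM in male replicate 15 and turned to -0.30 in limma-voom and -0.45 with surrogate variables. In edgeR 0 autosomal list members passed over all genes. The Y-linked and X lists were called also with an estimated correlation (adjusted p = 1.31e-38 and 1.1e-29 in camera). The other 10 of 12 calls, such as striatal (-0.25; 3.76e-05, and 0.881), ribosomal (-0.054; 4.64e-06, and 0.881) and oxidative phosphorylation genes (-0.050; 3.36e-06, and 0.881), did not hold.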

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

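Chosen only after the result was seen were the test of week 13 slopes by sex, all counts over shuffled animals, the fits with the choroid plexus score or without single libraries, the immediate early score of male replicate 39, and the reading of run as an explanation. The correlation of called genes with the choroid plexus score in males, and the distance of male replicate 39 over 12 list scores, were written down before they were computed.

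The change of preference from week 1 to week 13 differed between the sexes. It exceeded that of males by 0.103 in females (0.12 against 0.0177, permutation of sex p = 0.0189). With the means of the first and last 2 weeks the difference was 0.0529 (p = 0.161).

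Jchain, the joining chain of antibodies made by plasma cells, differed between the sexes in its week 13 slope, in a test of the difference itself. The male minus female difference was 3.41 ± 0.67 (edgeR adjusted p = 0.0323), from slopes of 1.73 in males and -1.69 in females, and it was the 1 gene called of 16320 (1017 at an unadjusted p under 0.05). Its highest libraries were male replicate 34 (15.5 CPM), female replicate 10 (12.5) and female replicate 25 (9.92), against a median of 0.612, and the antibody gene Ighm was highest in female replicate 10 and Igkc in female replicate 25. Week 13 preference was 0.571 in male replicate 34, 0.11 in female replicate 10 and 0.049 in female replicate 25. The test was not repeated without these libraries, so how far the difference rests on them is not known. Limma-voom called 0 genes for this difference. No explanation was tested.

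For week 13 preference in females, 1 of 100 orders of the females, the real one, gave 6 calls (highest other 4), while 26 of the others gave at least 1. A count of 6 was thus rare among free orders, which kept neither runs nor families together. The fit was set against them after its calls were seen, so chance is not fully excluded for that count. Chance cannot be excluded for the count at an unadjusted p under 0.05, where 10 orders gave at least the real 1415 (highest other 2493). Nor can it be for the choroid plexus and ependymal lists, which hold none of the 6 genes. EdgeR called 0 without female replicate 17 (1223 unadjusted) or 38 (950). The runs of sample-sheet numbers were argued against as the whole cause, since with run as a covariate slopes such as 2.03 for Col8a1 and 1.51 for Sema3b stayed. EdgeR then called 24 genes, but none below an adjusted p of 0.0498, so all lay at the threshold. Among them were 5 of the 6 genes at that value, while Corin (2.68) no longer passed (0.0779). A change in amygdala cells that does not go with choroid plexus RNA was argued against as the main part, because with the choroid plexus score as a covariate the median slope of the 6 genes was 0.74 and each call ended as its slope shrank, Col8a1 from 2.03 ± 0.39 to 0.44 ± 0.19 and Corin from 3.48 ± 0.62 to 0.81 ± 0.57, although Rrh kept 1.38 ± 0.42 of 2.94 and Sema3b 0.67 ± 0.21 of 1.48, so a part beyond the score stays open. RNA carried over from choroid plexus and ependyma in some dissections may explain most of it: the 6 genes had a median r of 0.869 with the score over the 41 males, where the score had an r of 0.00264 with week 13 preference, and Ttr, the most abundant choroid transcript, reached 23600 CPM in male replicate 38 and 21700 in male replicate 33, whose week 13 preference was 0.022, against a median of 55.9, although laser dissection should leave that tissue out. A choroid plexus that itself responds to drinking in females stays open as a biological explanation, was not tested, and cannot be separated from carry-over that went with preference in these females.

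The same explanation was tested on ethanol intake in females. The 2.1e2 calls (rounded) stood alone among 100 orders of the females (1 as large, the real one, highest other 44), while 36 of the others gave at least 1. Such a count was thus rare among free orders, which kept neither runs nor families together, so chance is not fully excluded for it. Chance cannot be excluded for the count at an unadjusted p under 0.05, where 12 of 100 gave at least the real 1568 (highest other 3108). With the choroid plexus score as a covariate, 0 of them stayed called (832 genes at an unadjusted p under 0.05, 97 of them intake calls outside the choroid plexus list), and the median size of slope of the calls outside that list fell from 1.19 (median SE 0.28) to 0.38 (0.23), which lies below 0.5 of its former size by less than 1 SE, so RNA carried over stays open. The scores of the choroid plexus and ependymal lists, which share no gene, had r = 0.927 over the 84 libraries, so the 2 sources could not be parted.

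Genes called for week 1 preference rested on male replicate 39, and edgeR called 0 genes without it. A large share of RNA from the cell types and regions of 12 lists was argued against, because over their scores this library lay at most 1.24 SD from the mean of the males. RNA from a source outside these lists could not be seen by that test and stays open. In male replicate 39, 9 genes stood more than 2 log2 units above the next library. A rise of activity-regulated transcription stays open, because its immediate early score lay only 1.09 SD above the mean of the males (0.781 without Bdnf and Nptx2), while 6 of the 26 genes of that list were highest of all libraries in it. Chance cannot be excluded, since 7 of 100 orders of the males gave at least 6 calls, and the highest other order gave 555 genes, many times the real count, which points to a structure of the samples, single outlying libraries included, that was not tested. An unusual animal or an unusual sample may lie behind it, and with 1 library these also stay open and untested.

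The lists called by camera with the preset correlation were as frequent without any relation to preference. At least as many lists as the real 11 in all animals came in 70 of 100 orders (highest other 22), at least the real 13 in females in 51 (highest other 23), and at least the real 8 in males in 92 (highest other 24), so chance cannot be excluded for these counts. Genes of 1 list vary together between libraries far more than a correlation of 0.01 allows, which may be the cause, since 0 lists passed with an estimated correlation. No biological explanation was tested.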

How the results depend on the processing

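Chosen only after the result was seen were the choroid plexus covariate, leaving out the 5 libraries with the highest choroid plexus score, leaving out single libraries, and the week 13 slope difference between the sexes with its alternatives. No paired analysis was possible because, for expression, replicate numbers follow the order of listing and each animal gave 1 library. Of 2583 values of the named gene results under an alternative, 2383 kept their direction and their side of the threshold, 91 no longer passed, 59 newly passed and 50 changed sign. Most of the named results did not pass in the main fit, so keeping their side mostly meant not passing again. The 91 losses fell only on results that had passed. The cause of a move was not tested unless a cause is given.

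For mean preference, edgeR called 0 genes in all animals (643 at an unadjusted p under 0.05), in females (1135) and in males (270), as did limma-voom, run as a covariate, DESeq2 size factors, a filter at 1 CPM, surrogate variables, both kinds of region score, rank of preference and leaving out the 2 extreme animals. With no low-count filter it called 53 genes (35 higher, 18 lower) in all animals, 23 (15 and 8) in females, 16 (11 and 5) in males, 21 (9 and 12) for the sex by preference term and 74 (23 and 51) for sex, where more genes of very low counts were tested. With ethanol intake in place of preference it called 8 in all animals and 2.1e2 (rounded) in females, and without the 5 libraries with the highest choroid plexus score 1 in each, Omp. DESeq2 called 2 genes in males, Npw and Tagap, and 1 for the sex by preference term, Npw, while run as a covariate gave 1 for that term.

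For week 1 preference, the 5 calls in all animals and 6 in males became 0 and 0 in limma-voom, 0 and 0 without the 2 extreme animals, which include male replicate 39, and 0 and 0 without male replicate 39 alone. Rank of preference gave 2 in all animals (1 higher, 1 lower), 0 in males and 1 in females, Slc6a3. In males DESeq2 called 3, run as a covariate 2 and the choroid plexus covariate 2. For week 13 preference in females, the 6 calls became 2.1e2 (rounded) in DESeq2 (15 lower, the others higher). With run as a covariate they became 24 (21 higher and 3 lower, with 5 of the 6), none below an adjusted p of 0.0498. They became 7 without the 2 extreme animals (the 6 among them) and 4 with the rank of preference (all among the 6). They became 0 in limma-voom, with the choroid plexus covariate, without the 5 libraries with the highest score, without female replicate 17 and without female replicate 38. In males DESeq2 called 2 (Npw and Vcp-rs), rank of preference 1 (Aldh3a1) and leaving out the 2 extreme animals 1 (Npw). The 1 gene whose week 13 slope differed by sex became 0 in limma-voom and 2 with run as a covariate.

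The 15 genes that differ by sex became 8 (1 higher, 7 lower in males) with the filter at 1 CPM in 42 libraries, which left out the 5 Y-linked genes, expressed in the 41 males alone, and Slc6a3 and Omp. They numbered 14 without female replicate 7, 14 without female replicate 15 and 16 without male replicate 36. The 11, 13 and 8 lists called for mean preference in all animals, females and males became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 in fry.

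Drinking results moved in 2 places. The sex difference passed for intake (2.41 g/kg, p = 0.00114) but not for preference, and the difference in the change of preference no longer passed over 2-week means (0.0529, p = 0.161). Over genes with a mean log2 CPM of at least 3, the agreement of female and male slopes changed from 0.249 to -0.059, and neither was beyond shuffled orders.

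Named genes that changed sign included some with large slopes, such as Cldn2 (2.75), Kl (2.62), F5 (2.49), Kcnj13 (2.23), Adh1 (1.95) and Clic6 (1.76) in females and Npw (3.46) in males for week 1. With surrogate variables these were, in females for mean preference, Adcy5 (0.012), Adh1 (-0.0078), Cfap65 (-0.16), Cldn2 (-0.41), Clic6 (-0.17), F5 (-0.33), Kcnj13 (-0.53), Kl (-0.11) and Pde1b (0.049), in all animals Crhr1 (0.11), Gabbr1 (4.6e-05), Grin2b (-0.036), Oprk1 (0.032) and Pde1b (0.0022), and for sex Pmch (-0.45). The choroid plexus covariate gave Crhr1 (0.083) and Grin2b (-0.010), with intake Crhr1 (0.050), and the region scores gave Crhr1 (0.0028) and Grin2b (-0.096). Without the 5 libraries with the highest choroid plexus score, Adh1 (-0.11) and Dnah11 (-0.074) in females and Crhr1 (0.087), Grin2b (-0.056) and Sst (0.011) in all animals changed sign, and with intake Adh1 (-0.039) and Crhr1 (0.040). Without male replicate 39, week 1 slopes did so in all animals for Cd28 (-0.039), Npw (-0.26), S100a3 (-0.11), Slc39a11 (-0.021) and Tdrd9 (-0.096), and in males for Klhl40 (-0.30), Npw (-0.96), Plekha2 (-0.054), S100a3 (-0.24), Slc39a11 (-0.029) and Tdrd9 (-0.20). Without the 2 extreme animals the values were -0.052 for Npw, -0.0030 for S100a3, -0.019 for Slc39a11 and -0.14 for Tdrd9 in all animals, -0.22 for Klhl40, -0.51 for Npw, -0.041 for S100a3, -0.042 for Slc39a11 and -0.39 for Tdrd9 in males, and -0.29 for Hdc in females. Limma-voom gave -0.16 for Npw in males and -0.30 for Pmch by sex.

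Some called genes had few counts, and small slopes were hard to detect. Npw, Cd28, Corin, Rrh and Sptlc3 had a mean log2 CPM below 1. In simulated counts edgeR recovered 28.4% of slopes of 0.5 in males and 43.3% in females, so smaller slopes were mostly not detectable with these animals.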

Other observations

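All tests in this part were chosen after the result was seen. The 15 genes that differ by sex were set against 100 assignments of the sexes, of which 2, the real one included, gave at least 15 calls. Most of the 15 are X- or Y-linked genes that the true labels must call, so this count tests little beyond the labels. Among the other assignments, 95 called at least 1 gene. Which genes they called was not kept, so this count cannot decide on chance for Slc6a3, Omp and Ddx4, which stays open. At an unadjusted p under 0.05, 59 of 100 gave at least the real 622 genes, so chance cannot be excluded for that count. The highest other assignment gave 106 genes, many times the real count, and points to a structure of the samples, single outlying libraries included, that was not tested. For week 1 preference in all animals, 11 of 100 orders gave at least 5 calls, with 662 the highest other.

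Single libraries carried RNA typical of other places. Female replicate 15 held 230 CPM of Slc6a3 (next library 4.45), 148 of Th (next 47.6), and 90.4 of Slc18a2, all genes of dopamine neurons. The oxytocin gene Oxt and vasopressin gene Avp reached 312 and 1500 CPM in female replicate 1 and 220 and 1110 in male replicate 22, against medians of 1.26 and 4.07. Pmch, the gene of melanin-concentrating hormone, reached 1040 CPM in male replicate 15 with a median of 1.09. Igkc reached 36.9 CPM in female replicate 25. Male replicate 39 also had the highest Srxn1 (356 CPM), Klhl40 (51.1, next 12.1), Slc39a11 (108, next 29.9) and Plekha2 (87.9, next 26.1), while its Fos, Arc and Npas4 ranked 6, 5 and 18 of 84.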
